A study of Mus musculus with 6 samples.

How the data were processed

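The study measured messenger RNA in NIH3T3 cells, an established mouse embryonic fibroblast line, after serum starvation. Per the labels' protocols, total RNA was taken up in TRIzol and 1 µg per sample entered the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and marks its strand. The 6 libraries fall into 3 wild-type and 3 RAI16 knockout samples, grouped and numbered by their titles. The labels do not say whether libraries of a group came from separate cultures or from separate clones. The p-values therefore measure the spread between these libraries, which may be technical. The lesion that made the knockout is not given in the sources used here.

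The authors' first table holds raw read counts per gene as whole numbers, whose sums differ between libraries. The authors' other table holds FPKM values for the same genes. Over 84086 values above 0, the deposited FPKM differed by at most 8.04e-05% from the count divided by the library's total and by a single length per gene, and it is 0 exactly where the count is 0. That length was derived from the same counts and FPKM values as a median over libraries. The check therefore covers only agreement between libraries. Gene lengths given below are these derived lengths, known up to a common factor. Per the submitters' processing notes, Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq were used with the mouse build GRCm39. Their versions and settings, the annotation release and the strand setting of the counting are not given in the sources used here. If strand was not used, reads of a gene and of an overlapping antisense gene cannot be told apart. Genes with near-identical copies, such as those for ribosomal proteins and the Akr1c, Kng and Oas families, are uncertain because the treatment of shared reads is not given.

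Both tables list 16000 genes by symbol and NCBI gene number, and 0 columns belong to other samples. A list of 13 mitochondrially encoded genes had 0 members tested, and these genes were not analysed here. Total counts ran from 16741607 to 18368760 per library. The 10 most abundant genes took from 5.48% to 5.91% of the counts. Counting error is the only error that the intervals on count ratios cover (exact binomial, 95%), and PCR copies are not independent molecules.

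Genes were kept with edgeR's filterByExpr, which left 11972 genes holding at least 99.9% of the counts of each library. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), knockout against wild type, with no other term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and fold changes were counted again at 2-fold or more. Fold changes are given as log2 of knockout over wild type with their standard error, and levels as CPM, the count scaled to the library's TMM-adjusted total, with the SD over the 3 libraries of a group. Fold changes come from the fitted model. Their standard error was not estimated by the fit. It was taken as the size of the log2 fold change divided by the square root of the test's F statistic. Intervals on fold changes were built from this standard error. For large changes with few counts in a group it can be too small, and the counting intervals given below for several such genes are wider. The fitted fold of a gene with 1 to 3 counts in a group depends on the model's prior count, so for such genes the ratio of the summed counts is given with its counting interval.

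The 32 gene lists (753 entries) were written before the data were examined. They cover the FHF complex and dynein adaptors, Hedgehog pathway, cilium assembly, cAMP and PKA signalling, DNA replication, mitosis, p53 response, immediate early genes, collagens and matrix, matrix proteases and inhibitors, contractile cytoskeleton, YAP and TAZ targets, TGF-beta and BMP signalling, Wnt signalling, cholesterol synthesis and uptake, adipogenesis and fatty acid synthesis, interferon response, NF-kappaB targets and chemokines, ER stress and integrated stress response, lysosome and autophagy, oxidative phosphorylation, glycolysis and hypoxia, NRF2 antioxidant response, retinoic acid pathway, growth factor ligands and receptors, cytosolic ribosome and mitochondrially encoded genes. The other lists are markers of epithelial, leukocyte, endothelial, muscle and neural cells. Of the entries, 714 were in the tables and 628 were tested. Lists with at least 5 tested genes were compared with all other genes by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry were run beside it. The count of members called was also adjusted over the list alone.

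The genes named were fixed by rule before the data were examined. They are the targeted gene, then the 12 largest rises and the 12 largest falls in log2 fold change. These were taken among called genes with a mean of at least 5 CPM over the 6 libraries, no overlap between the groups and a symbol that is not a predicted or clone name. For each list, up to 4 tested members with the smallest adjusted p were added. Some genes under this rule are not reported here. Genes outside this rule are marked as chosen after their values were seen.

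The main test was tested on simulated counts for the knockout against wild-type comparison, with 200 genes changed. Means came from the wild-type libraries and sizes from all libraries. Changed genes were picked only among those with a wild-type mean above 1 CPM, so recovery at lower levels was not tested. It recovered 87% of genes changed 1.5-fold (11799 genes run), 94.5% of those changed 2-fold (11802) and 99.5% of those changed 4-fold (11803). From 5.24% to 7.35% of its calls were false. In the real comparison 59.6% of the genes were called, far more than were changed here, so these shares need not hold there. Camera, run on 11972 simulated genes with 1 list shifted 2-fold, called 1 of 28 lists, the shifted one. Simulated genes were drawn independently of each other, so this run does not test camera on genes that move together.

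Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile and plain library-size scaling, no filter, a filter of 1 CPM in at least 3 libraries, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, limma-trend on log2 of FPKM with a pseudocount of 1 or 0.1 and with or without a filter of 1 FPKM in at least 3 libraries, an adjusted p of 0.01, a test against a 1.5-fold change, the replicate number as a block, and each library left out in turn. Removing each library's trend on gene length was added after seeing the data. A direction was counted as reversed only for a gene or list that passed under at least one of the settings compared. Splits of the 6 libraries into 3 and 3 numbered 10.

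Positions served the closing section and the window results given before it. NCBI's RefSeq annotation of GRCm38.p6 was used for gene order and chromosome, not for coordinates, because the deposited counts were made on another build. By gene number, 11941 of 11972 tested genes matched, 99.96% of these with the same symbol, and 11719 were placed on a chromosome. A gene was placed if the GENCODE annotation of GRCm38 also put its symbol on that chromosome. GC was taken from the longest GENCODE transcript of the symbol. Windows of 20 neighbouring tested genes were compared with 1000 shuffles of gene order. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.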

Results

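RNA of serum-starved NIH3T3 fibroblasts was sequenced in 3 libraries of wild-type cells and 3 libraries labelled RAI16 knockout. The comparison asked which transcripts differ between knockout and wild-type cells when serum is withdrawn, a treatment that takes fibroblasts out of the cell cycle and lets them form primary cilia. Wild-type replicates 1, 2 and 3 held 17388612, 16741607 and 17482451 counts. Knockout replicates 1, 2 and 3 held 18368760, 18174473 and 17805417. The first principal component separated the groups and held 88.1% of the variance of log2 CPM. The next held 5.90% and set knockout replicate 2 (score 23.3) apart from knockout replicates 1 and 3 (−12.0 and −12.2). Counts of replicates 1 and 3 of the knockout differed by a chi-square of 1.72 per degree of freedom, and those of replicate 2 from them by 29.7 and 27.6. Wild-type pairs lay between 1.92 and 2.28. All replicate pairs differed by more than sampling noise, so each library was counted once.

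The targeted gene is listed as Fam160b2 (gene number 239170), another symbol of Rai16 or Fhip2b, which encodes a member of the FHIP protein family. Its transcript was not lower by test in the libraries labelled knockout. Wild-type replicates 1, 2 and 3 had 440, 375 and 411 counts, and knockout replicates 1, 2 and 3 had 410, 394 and 390. In CPM each knockout library (22.3, 21.5 and 22.0) lay below each wild-type library (25.4, 22.5 and 23.6). The mean was 23.8 ± 1.49 CPM in wild type and 21.9 ± 0.395 CPM in knockout (SD, n = 3 each). The log2 fold change was −0.12 ± 0.075 (SE), with a 95% interval from −0.29 to 0.05 and an adjusted p of 0.184 in edgeR's quasi-likelihood test. A whole-gene count does not check a small insertion or deletion, whose transcript can persist, so the labels rest on the titles and genotype entries alone. The 20 neighbouring genes of its window had a median log2 fold change of −0.70. Of its relatives, Fam160a1 lay at 20.2 ± 0.735 CPM in wild type and 20.2 ± 0.562 CPM in knockout, and Fam160b1 at 77.1 ± 5.09 and 77.1 ± 9.82 CPM. Fam160a2 lay at 32.8 ± 1.04 and 38.4 ± 4.41 CPM (adjusted p = 0.0507). These relatives were named after their values were seen.

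The libraries labelled knockout differed from wild type in most genes tested. Thbs1, Msln, Lum and Dkk2 were far higher in them, and Grem1, Serpine2, Pcdh7 and Ndn were far lower. Of 11972 genes, 7136 changed (59.6%), 3646 of them higher and 3490 lower in knockout. Most changes were small: the median size among the called genes was 1.42-fold. At least 2-fold changes were found for 1299 genes, 517 higher and 782 lower, and fitted changes of at least 16-fold for 41 genes higher and 96 lower. The groups did not overlap in CPM for 67.6% of the genes, where chance gives 10%. The spread behind these tests was narrow, with a biological coefficient of variation of 7.76%. Genes often moved with their neighbours on the chromosome: 37 of 576 windows of 20 genes had a median log2 fold change of at least 0.5 in size.

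**Figure D1:**
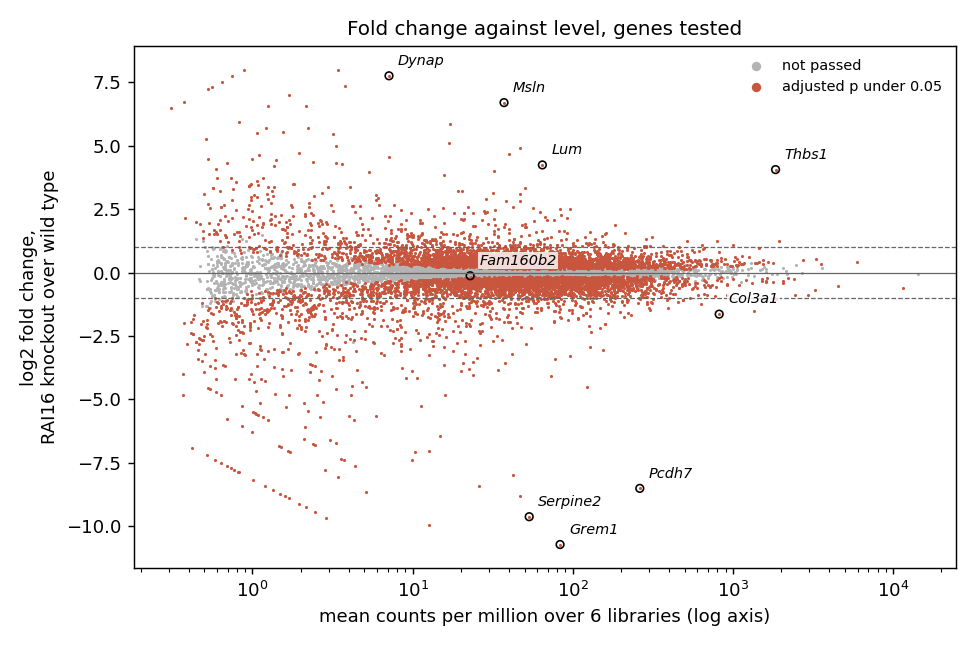
Log2 fold change of knockout over wild type (vertical axis) against the mean CPM over 6 libraries (horizontal log axis), with 1 point per gene for the 11972 genes tested and dashed lines at a 2-fold change. Coloured points are the 7136 genes that changed, circles mark named genes, and the points that line up at the lower left are genes with few or no counts in knockout, whose fitted fold depends on the prior count.

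The 12 largest rises ended between 10.1 CPM (Ccl17) and 3484 CPM (Thbs1) in knockout. Thbs1, the matrix glycoprotein thrombospondin 1, rose from 208 ± 8.81 CPM in wild type to 3484 ± 539 CPM in knockout (SD, n = 3 each), a log2 fold change of 4.06 ± 0.12 (SE; adjusted p = 3.3e-08, edgeR). The matrix proteoglycan lumican, Lum, rose from 6.46 ± 0.156 to 123 ± 3.53 CPM. Msln, encoding the surface protein mesothelin, rose from 0.702 ± 0.0725 to 73.7 ± 3.4 CPM, and Dkk2, a secreted modulator of Wnt receptors, from 3.01 ± 0.446 to 91.1 ± 2.76 CPM. Sema3c, a secreted semaphorin, rose by 5.87 ± 0.22 on the log2 scale, and the kininogen gene Kng2 by 5.10 ± 0.15. Akr1c18, whose product inactivates progesterone, went from 2.98 ± 0.513 to 77.3 ± 8.3 CPM. B3gnt3, a glycosyltransferase, rose by 4.57 ± 0.19, the X-linked homeobox gene Rhox5 by 4.02 ± 0.15, the chemokine gene Ccl17 by 3.95 ± 0.20 and the pantetheinase gene Vnn1 by 3.85 ± 0.11 on the same scale. Dynap had 3 counts in all wild-type libraries and 774 in knockout, a ratio of wild type to knockout of 0.00408 (95% counting interval 0.00084 to 0.012). Its fitted log2 fold change of 7.76 became 8.63 without wild-type replicate 2. Adjusted p over these 12 genes ran from 9.7e-10 to 7.65e-07.

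The 12 largest falls were in genes at 10.2 to 523 CPM in wild type, none of which averaged over 1.43 CPM in the libraries labelled knockout. Grem1, a secreted antagonist of BMP ligands, fell from 167 ± 4.57 CPM to 0.0913 ± 0.0303 CPM (SD, n = 3 each; log2 fold change −10.72 ± 0.13, adjusted p = 3.35e-10, edgeR). It had 8554 counts in wild type and 5 in knockout, a ratio of 1801 (95% counting interval 772 to 5550). This interval is wider than the standard error implies. Pcdh7, a protocadherin, fell from 523 ± 8.17 to 1.43 ± 0.392 CPM, and Serpine2, the protease inhibitor nexin, from 107 ± 2.61 to 0.128 ± 0.0825 CPM. The fitted log2 fold change of Serpine2, −9.62 with all libraries, became −10.21 without knockout replicate 2. Actr3b, a relative of the actin nucleator subunit Arp3, fell from 93.0 ± 6.28 to 0.201 ± 0.0281 CPM, and the neurturin receptor gene Gfra2 from 84.6 ± 1.74 to 0.329 ± 0.142 CPM. Bnc1, a zinc-finger gene, went from 52.0 ± 1.78 to 0.147 ± 0.033 CPM. Enpp5, Eml2, Serpinb8 and Sgk3 fell with log2 fold changes of −6.44 ± 0.14, −7.05 ± 0.27, −7.40 ± 0.26 and −5.67 ± 0.23. In the same order they had 18, 10, 6 and 12 counts in knockout. Their ratios of wild type to knockout were 87.9 (95% counting interval 55.4 to 149), 136 (73.9 to 285), 178 (81.7 to 488) and 52.2 (29.7 to 102). These intervals are wider than the standard errors imply. The imprinted gene Ndn (necdin) had 1292 counts in wild type and 1 in knockout, a ratio of 1360 (95% counting interval 244 to 53778). Rab6b, a small GTPase gene, had 527 counts against 1, a ratio of 555 (99.2 to 21960). The single counts lay in knockout replicate 2 for Ndn and in replicate 1 for Rab6b, and without those libraries the fitted log2 fold changes were −11.78 and −10.49. Adjusted p over the 12 genes ran from 3.35e-10 to 4.84e-07.

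**Figure D2:**
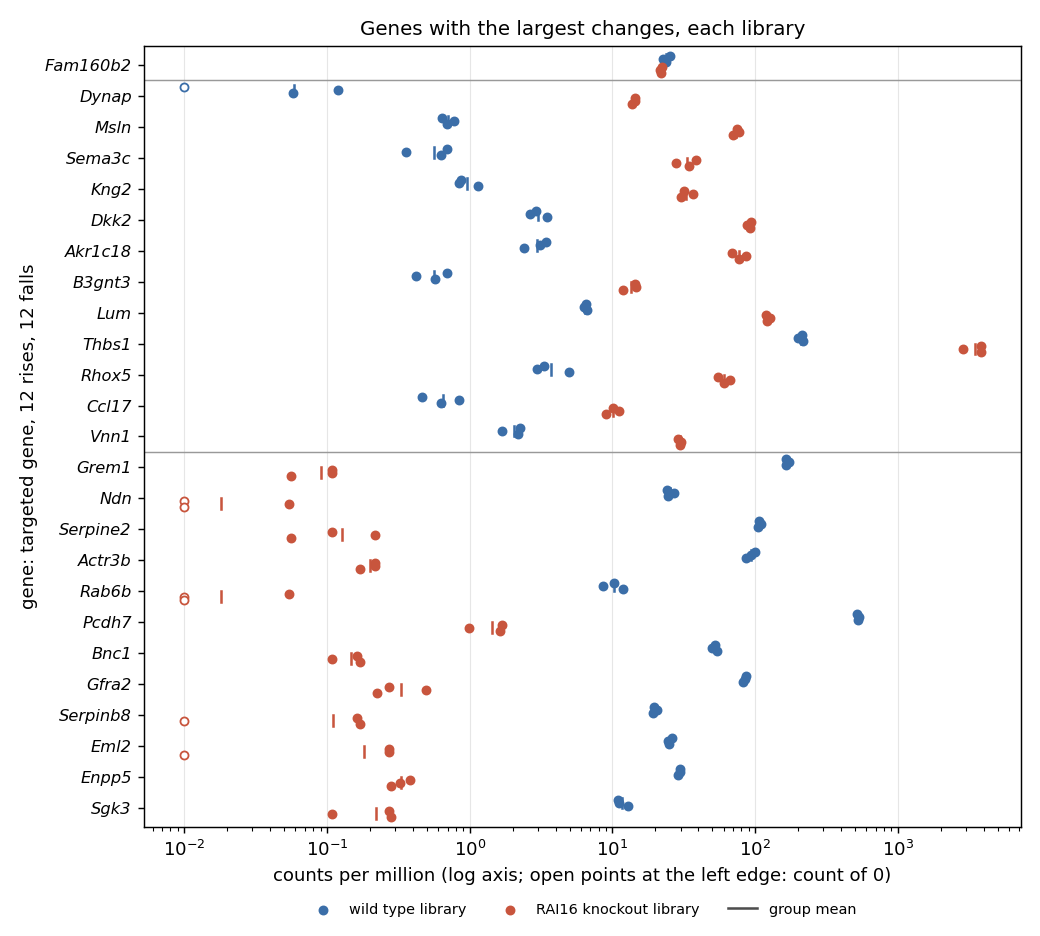
CPM of each library (horizontal log axis) for the targeted gene Fam160b2, the 12 genes with the largest rises and the 12 with the largest falls, with wild type in blue, knockout in red, group means as bars and open points for a count of 0. For Fam160b2 the libraries of both groups lie between 21.5 and 25.4 CPM, while in the other rows the groups are far apart.

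Among the gene lists, genes of cholesterol synthesis and uptake were higher in knockout with the smallest p. Of 23 tested, 21 rose and 0 fell, and adjusted over the list alone 22 rose. The median log2 fold change was 0.80, and the list stood above other genes in camera (adjusted p = 1.43e-07 with the preset correlation, 0.335 with an estimated correlation). Mvd, the mevalonate diphosphate decarboxylase gene, rose by 1.92 ± 0.076 on the log2 scale, from 20.9 ± 1.38 to 79.1 ± 4.89 CPM. The lanosterol demethylase gene Cyp51 rose by 1.39 ± 0.062 and the HMG-CoA synthase gene Hmgcs1 by 1.05 ± 0.054. Hsd17b7, named after its value was seen, did not pass (0.17 ± 0.068, adjusted p = 0.0579).

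Cell-cycle genes were also higher. Of 26 mitosis genes 21 rose and 0 fell, with a median of 0.51 (adjusted p = 8.05e-06; adjusted p = 0.335 with an estimated correlation). The mitotic kinase genes Plk1 and Aurkb rose by 1.05 ± 0.064 and 0.99 ± 0.067 on the log2 scale. Bub1, of the spindle checkpoint, rose by 0.69 ± 0.060, and the cytokinesis kinesin gene Kif20a by 0.64 ± 0.056. Of 26 genes of DNA replication 19 rose and 3 fell, 20 and 3 adjusted over the list alone, with a median of 0.54 (adjusted p = 4.20e-04; adjusted p = 0.659 with an estimated correlation). Rrm2 and Rrm1, the subunits of ribonucleotide reductase, rose by 1.30 ± 0.068 and 0.75 ± 0.062. The helicase gene Mcm2 rose by 1.04 ± 0.063 and cyclin E1 (Ccne1) by 0.87 ± 0.073. The members that fell were Mcm3 (−0.60 ± 0.059), Mcm6 (−0.19 ± 0.060) and Pola1 (−0.38 ± 0.094), named after their values were seen. Mcm2, Mcm3 and Mcm6 encode subunits of the same helicase, and they moved in both directions.

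For every other list of pathway genes the camera test did not pass, although each of them held members that rose and members that fell. The count adjusted over the list alone equals that over all genes unless it is given. The lists nearest to the targeted gene were among these. Of 17 genes of the FHF complex and dynein adaptors, 4 rose and 4 fell (median −0.00061, adjusted p = 0.963). The dynein light intermediate chain gene Dync1li1 fell by 0.80 ± 0.053 on the log2 scale, from 102 ± 1.43 to 58.6 ± 1.38 CPM, and the adaptor gene Bicd2 fell by 0.28 ± 0.055. The dynactin gene Dctn1 rose by 0.55 ± 0.053 and the adaptor gene Hook2 by 0.56 ± 0.063. Of 18 Hedgehog genes, 6 rose and 9 fell (median −0.13, adjusted p = 0.678). The co-receptor genes Cdon and Gas1 fell by 2.34 ± 0.13 and 0.58 ± 0.058, the transcription factor gene Gli2 by 1.19 ± 0.11 and Foxl1 by 1.27 ± 0.10. Of 33 genes of cilium assembly, 9 rose and 10 fell (median −0.03, adjusted p = 0.853). Dync2h1, the motor of retrograde transport in cilia, fell by 1.77 ± 0.13, the transport genes Ift88 and Ift81 by 0.72 ± 0.089 and 0.48 ± 0.066, and Bbs9 by 0.89 ± 0.097. Of 27 genes of cAMP and PKA signalling, 8 rose and 9 fell, 8 and 10 adjusted over the list alone (median 0.13, adjusted p = 0.85). The phosphodiesterase genes Pde4b and Pde4d rose by 1.63 ± 0.082 and 1.11 ± 0.081, while the PKA catalytic subunit gene Prkacb fell by 0.86 ± 0.076 and Creb1 by 0.70 ± 0.066. Changes of members in all lists were not separated from shifts of their neighbours on the chromosome. Hook2, for example, lay in a window on chromosome 8 with 11 rises and 1 fall. Gli2 lay in a window on chromosome 1 with 4 rises and 13 falls. Other members were not compared with their windows.

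Genes of growth control and of the response to serum were mixed. Among 27 immediate early genes 9 rose and 15 fell, 10 and 15 adjusted over the list alone (median −0.37, adjusted p = 0.317). The phosphatase gene Dusp1 and the nuclear receptor gene Nr4a1 rose by 2.07 ± 0.071 and 1.11 ± 0.067 on the log2 scale. The transcription factor genes Egr3 and Egr1 fell by 1.73 ± 0.11 and 0.83 ± 0.055. Growth factor ligands and receptors counted 8 rises and 9 falls among 23 (median −0.13, adjusted p = 0.678), with lower Fgfr2 (−1.38 ± 0.067), Fgf10 (−0.96 ± 0.057) and Ereg (−0.91 ± 0.063) and higher Pdgfc (1.03 ± 0.067). The p53 response counted 7 rises and 4 falls among 18 (median 0.17, adjusted p = 0.372). Ccng1 rose by 1.22 ± 0.063, Btg2 by 1.16 ± 0.12, the death receptor gene Tnfrsf10b by 0.89 ± 0.079 and Sesn1 by 0.75 ± 0.093.

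Matrix genes held some of the strongest single changes, again in both directions. Of 29 collagen and matrix genes 14 rose and 9 fell (median 0.11, 0.30 without knockout replicate 2; adjusted p = 0.338). Beside Thbs1 and Lum, the named members were periostin (Postn), from 31.0 ± 1.14 to 1.08 ± 0.372 CPM, and the fibrillar collagen gene Col3a1, from 1242 ± 15.3 to 399 ± 13.4 CPM, with log2 fold changes of −4.83 ± 0.16 and −1.64 ± 0.055. Among 21 matrix proteases and inhibitors 7 rose and 9 fell (median −0.09, adjusted p = 0.682). Beside Serpine2, Mmp9 fell by 1.58 ± 0.065 and Adamts2, which trims procollagen, by 0.76 ± 0.066, and Adamts1 rose by 1.35 ± 0.096. The contractile cytoskeleton counted 10 rises and 4 falls among 19 (median 0.22, adjusted p = 0.294). Calponin 2 (Cnn2) rose by 1.89 ± 0.083 and the myosin genes Myh10 and Myl6 by 0.87 ± 0.090 and 0.76 ± 0.085, and the myosin light chain kinase gene Mylk fell by 1.19 ± 0.10. Among 20 YAP and TAZ targets 7 rose and 8 fell (median 0.04, adjusted p = 0.896). Ccn2, the connective tissue growth factor, rose from 6.54 ± 0.11 to 57.1 ± 2.11 CPM, Ankrd1 rose by 1.82 ± 0.082 and Amotl2 by 1.07 ± 0.054, whereas Gadd45a fell by 1.59 ± 0.071.

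TGF-beta and BMP signalling counted 9 rises and 12 falls among 26 genes, 10 and 12 adjusted over the list alone (median −0.11, adjusted p = 0.693). Beside Grem1, the matrix gene Tgfbi rose by 3.23 ± 0.092 on the log2 scale, and the procollagen protease gene Bmp1 and the latent TGF-beta binding protein gene Ltbp2 fell by 0.82 ± 0.053 and 1.08 ± 0.075. Wnt signalling counted 7 rises and 6 falls among 17 (median −0.04, adjusted p = 0.927). Lef1, a transcription factor of the pathway, fell from 42.1 ± 1.08 to 2.99 ± 0.152 CPM, and Dkk3 rose from 28.4 ± 1.60 to 164 ± 5.82 CPM, beside the rise of Dkk2. Sfrp2, a secreted Wnt inhibitor, had 352 counts in wild type and 1 in knockout, a ratio of 371 (95% counting interval 66.1 to 14681). Its fitted log2 fold change of −8.07 became −9.91 without knockout replicate 2, which held the count, and the median of the list was −0.04 also with Sfrp2 at the bound of this interval.

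Stress genes included several strong falls. All 24 genes of ER stress and the integrated stress response changed, 12 up and 12 down (median −0.03, adjusted p = 0.678). The members named all fell: Trib3 by 2.81 ± 0.081 on the log2 scale, the glutathione-degrading enzyme gene Chac1 by 2.19 ± 0.089, the transcription factor gene Atf5 by 1.60 ± 0.063 and Psat1, of serine synthesis, by 1.25 ± 0.057. In the NRF2 antioxidant response 5 of 18 genes rose and 9 fell, 5 and 11 adjusted over the list alone (median −0.21, adjusted p = 0.317). The cystine transporter gene Slc7a11 fell from 138 ± 2.79 to 8.20 ± 0.997 CPM, the heme oxygenase gene Hmox1 from 350 ± 7.25 to 109 ± 6.41 CPM, and Gclc, of glutathione synthesis, from 95.9 ± 5.11 to 41.6 ± 1.24 CPM, while the transketolase gene Tkt rose by 0.59 ± 0.058. Of 30 interferon response genes 12 rose and 8 fell, 12 and 9 adjusted over the list alone (median 0.08, adjusted p = 0.85). Cxcl10 fell from 226 ± 0.678 to 29.8 ± 2.04 CPM, Oasl1 fell by 2.46 ± 0.12 and Oas2 by 0.84 ± 0.065, and Bst2 rose by 1.23 ± 0.085. NF-kappaB targets and chemokines counted 10 rises and 12 falls among 26 (median −0.10, adjusted p = 0.853). The cytokine gene Il33 fell by 3.54 ± 0.12 and Cxcl12 by 1.04 ± 0.053, and Lcn2 and Il6 rose by 2.39 ± 0.081 and 1.48 ± 0.10.

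The metabolic lists did not pass the list test either. Adipogenesis and fatty acid synthesis counted 6 rises and 3 falls among 13 genes, 8 and 3 adjusted over the list alone (median 0.27, adjusted p = 0.317). The named members rose: Fasn by 0.85 ± 0.10 on the log2 scale, Acly by 0.78 ± 0.076, Elovl6 by 0.62 ± 0.078 and the transcription factor gene Cebpd by 0.69 ± 0.10. Glycolysis and hypoxia genes counted 7 rises and 9 falls among 23 (median −0.07, adjusted p = 0.605). Adm, encoding adrenomedullin, rose from 19.8 ± 0.234 to 104 ± 4.28 CPM, and the glucose transporter gene Slc2a1, Vegfa and Ankrd37 fell by 0.98 ± 0.053, 0.95 ± 0.056 and 1.05 ± 0.10. Among 25 genes of lysosome and autophagy 12 rose and 6 fell, 12 and 8 adjusted over the list alone (median 0.22, adjusted p = 0.678). The cathepsin genes Ctsk and Ctsl fell by 3.19 ± 0.089 and 0.87 ± 0.077, the proton pump gene Atp6v1h by 0.90 ± 0.059, and Ctsa rose by 0.60 ± 0.062. The retinoic acid pathway counted 5 rises and 6 falls among 13 (median 0.02, adjusted p = 0.896), with higher Tgm2 (1.54 ± 0.099) and Rdh10 (0.89 ± 0.079).

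The medians of lists that were not called depended on single libraries, knockout replicate 2 most often. Of 34 genes of oxidative phosphorylation 12 rose and 3 fell, 11 and 3 adjusted over the list alone (median 0.19, adjusted p = 0.543). Ndufs1 fell by 0.44 ± 0.063 on the log2 scale, and Ndufa8, Ndufb10 and Ndufv1 rose by 0.56 ± 0.11, 0.41 ± 0.098 and 0.39 ± 0.084. Of 34 cytosolic ribosome genes 9 rose and 2 fell, 7 and 2 adjusted over the list alone (median 0.09, adjusted p = 0.678). Rps2, Rpl32 and Rps6 rose by 0.58 ± 0.10, 0.52 ± 0.10 and 0.39 ± 0.10, and Rpl7 fell by 0.40 ± 0.094. With the genes split into 4 equal groups by length, the shortest (median 1530 bases) lay 0.24 above the mean of the other knockout libraries on the log2 scale in replicate 2, and the longest (median 8169 bases) lay at −0.25. Without that library the median of the oxidative phosphorylation list was 0.06, with 13 rises and 11 falls, and that of the ribosome list −0.03, with 12 rises and 16 falls. In all, 14 of 28 medians turned or moved by over 1.5 times without it, none of them of a called list. Beside the ribosome list, those that turned were the FHF complex and dynein adaptors (0.02), cilium assembly (0.01), Wnt signalling (0.12) and the retinoic acid pathway (−0.23). The collagen and matrix list lay at 0.30, YAP and TAZ targets at 0.16, NF-kappaB targets and chemokines at −0.18, lysosome and autophagy at 0.13, glycolysis and hypoxia at −0.13, growth factor ligands and receptors at −0.08, the interferon response at 0.04 and ER stress at −0.02. Leaving out another library moved from 3 to 11 medians this way. Beyond the lists above, these were TGF-beta and BMP signalling (−0.17), cAMP and PKA signalling (0.08), matrix proteases and inhibitors (−0.06) and neural markers (−0.32), all without knockout replicate 3. The median of the YAP and TAZ targets turned to −0.05 without knockout replicate 1 and to −0.04 without knockout replicate 3. Counts of 12 lists moved by over 1.5 times with a library left out. Without wild-type replicate 1 the Hedgehog list had 2 rises and the glycolysis and hypoxia list 3. Without wild-type replicate 2 the FHF list had 2 falls and the ribosome list 5 rises. Without wild-type replicate 3 oxidative phosphorylation had 6 rises, cilium assembly 6 falls and the adipogenesis list 1 fall. Without knockout replicate 2 the cAMP list had 13 rises, the p53 response and the YAP and TAZ targets 11 each, DNA replication 5 falls and mitosis 1 fall.

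Many markers of other cell types had too few counts to be tested. Endothelial markers passed the list test: of 5 tested 4 rose and 0 fell, all 5 rose when adjusted over the list alone, and the median was 0.94 (adjusted p = 0.0318; adjusted p = 0.414 with an estimated correlation). The call was lost with an adjusted p of 0.0805 without wild-type replicate 1, 0.101 without wild-type replicate 3, 0.0581 without knockout replicate 2 and 0.251 without the filter on low counts. The VEGF receptor gene Flt1 rose from 6.23 ± 0.478 to 21.5 ± 2.77 CPM, Eng from 1.42 ± 0.191 to 2.73 ± 0.0642 CPM, Egfl7 from 2.35 ± 0.324 to 4.10 ± 0.795 CPM and Cdh5, an endothelial cadherin, from 0.216 ± 0.128 to 1.76 ± 0.887 CPM. The other 9 markers, Pecam1 and Kdr among them, had too few counts to be tested. Neural markers counted 2 rises and 2 falls among 5, 2 and 3 adjusted over the list alone (median −0.50, adjusted p = 0.835). Nes, encoding nestin, rose by 4.99 ± 0.28 on the log2 scale (5.69 without wild-type replicate 1), Ncam1 rose by 0.62 ± 0.075, and Map2 fell by 2.78 ± 0.19. Lists with fewer than 5 tested genes were not put to the list test. Of 4 leukocyte markers 2 rose (Csf1r, 2.20 ± 0.38, and Cd68, 0.51 ± 0.13) and 2 fell (Aif1, −1.28 ± 0.29, and Cd14, −0.45 ± 0.11). Of 2 epithelial markers Krt8 rose by 2.04 ± 0.22 and Muc1 did not pass (−0.17 ± 0.26), and of 2 muscle markers Tnnc1 rose by 1.16 ± 0.28 and Des did not pass (1.48 ± 1.00). Of 13 mitochondrially encoded genes 0 were tested.

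Median, mean and test did not share a sign in 5 lists. The mean log2 fold change was −0.43 for Wnt signalling, where camera pointed up, −0.06 for interferon response and −0.05 for lysosome and autophagy, where it pointed up with the median. For the retinoic acid pathway the mean was −0.12 and camera pointed down, against the median, and for neural markers the mean was 0.11 with camera and the median pointing down.

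**Figure D3:**
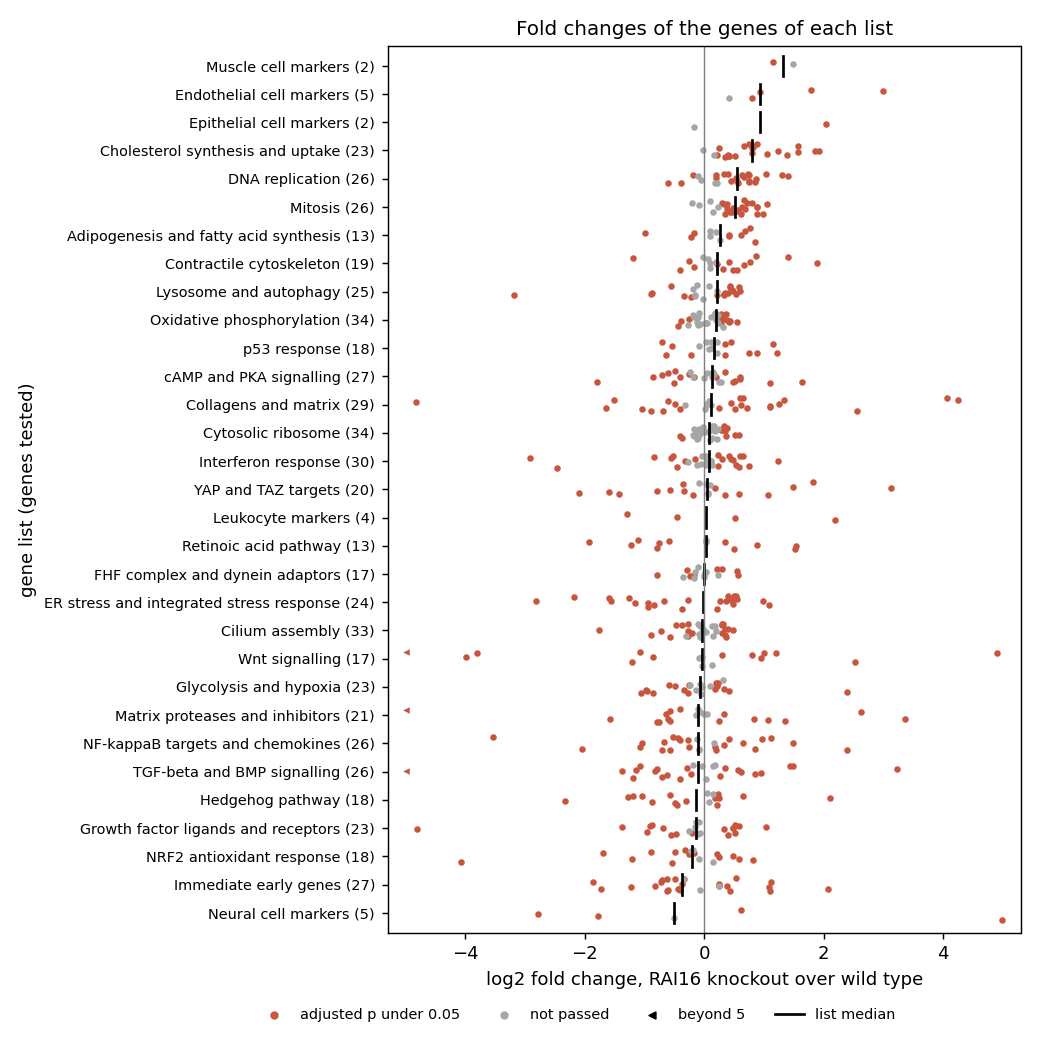
Log2 fold change of knockout over wild type (horizontal axis) of each tested member of the 31 lists with a tested gene, with 1 point per gene, coloured where the adjusted p passed, a black bar at the list median, and arrowheads for values beyond the axis. Points of the cholesterol, mitosis and DNA replication lists lie mostly to the right of 0 (medians 0.80, 0.51 and 0.54), and those of most other lists spread to both sides.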

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

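The removal of each library's length trend was chosen after seeing the data; the other alternatives here were fixed before the data were examined. The count of genes changed stayed within 1.5 times of 7136 under each of them, from 5465 at an adjusted p of 0.01 to 8586 without knockout replicate 2. Leaving out 1 library gave 6048 to 8586, and removing the length trend gave 8032. Without knockout replicate 2, 7050 of the 7136 calls were kept with the same sign. Over the settings at an adjusted p of 0.05 from 83.5% to 98.9% of the calls were kept, and the share higher in knockout lay between 49.6% and 53.7%. The median of all genes lay between −0.0083 and 0.024 on the log2 scale over the settings. The count of at least 2-fold changes, 1299, ran from 1155 to 1551 with counts, and 1694 genes passed a test against a 1.5-fold change. From FPKM it was 545 (pseudocount 1, filtered), 809 (pseudocount 0.1, filtered) and 546 (pseudocount 1, no filter), where input and test differ as well. Leaving out 1 library gave 1329 to 1397. The targeted gene did not pass under any setting, with log2 fold changes from −0.16 to −0.08 and adjusted p from 0.122 to 0.478.

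Of 28 lists, 4 were called, and 3 or 4 with other scalings, no filter or 1 library left out. With an estimated correlation camera called 0. Fry, which asks whether members move on balance and does not compare a list with other genes, called 20, 9 up and 11 down, and 28 in its mixed form. Interferon response was called down in fry (adjusted p = 0.0338; 0.0338 to 0.970 over its alternatives) and not called in camera (adjusted p = 0.85). Over the alternatives the adjusted p ran from 5.3e-09 to 0.335 for cholesterol synthesis and uptake, from 6.77e-07 to 0.335 for mitosis, from 8.27e-05 to 0.659 for DNA replication and from 1.01e-04 to 0.414 for endothelial markers. Of 139 named genes, 0 reversed, and 1 lost its call, Rps6 with FPKM and no filter (adjusted p = 0.061; 4.52e-14 to 0.061 over its alternatives).

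The groups share replicate numbers, but libraries of the same number did not deviate together (r = −0.07, −0.09 and 0.02 across genes), and not every library correlated best with its own number. With the replicate number as a block, 6692 genes changed, 1300 of them at least 2-fold, 4 lists were called and the targeted gene lay at −0.12. At this depth the test recovered 87% of 1.5-fold changes in a simulation with far fewer changed genes than the data. The changed genes there all lay above 1 CPM in wild type. Genes that did not pass may hold small changes.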

Other observations

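The tests of the length trend and of a wrong label or of wild-type cells in knockout replicate 2, of DNA copy number, of the neighbours of fallen genes and of splits of the libraries, except the split by chromosome, and the genes named here were chosen in their present form after the results were seen. Counting those of the report, 38 genes with at least 5 CPM in wild type fell at least 16-fold in the libraries labelled knockout. Among those not yet described were Gpnmb, a transmembrane glycoprotein (234 to 10.2 CPM), Tnr, the matrix protein tenascin R (45.0 to 2.73 CPM), the epithelial transcription factor gene Ehf (22.0 to 0.569 CPM), the tubulin gene Tubb2b (17.3 to 0.970 CPM) and the lipoprotein receptor gene Vldlr (311 counts to 3, a ratio of wild type to knockout of 109, 95% counting interval 37.0 to 532). In the other direction, 16 genes with at least 5 CPM in knockout rose at least 16-fold, again counting those of the report. Among those not yet described were the kininogen gene Kng1 (1 count in wild type and 371 in knockout, ratio 0.00284, 0.0000717 to 0.0159), the butyrophilin gene Btn1a1 (2 and 411 counts, ratio 0.00512, 0.000618 to 0.0186), Ripk3, a kinase of necroptosis (0.136 to 6.26 CPM), and Gdf5, a BMP-family ligand (0.350 to 6.90 CPM).

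Whole chromosomes differed in their typical fold change. By camera 12 of 21 chromosomes stood apart from the rest at an adjusted p under 0.05, 10 with an estimated correlation, 13 without knockout replicate 2 and 14 with the length trend removed. Leaving out that library and removing the length trend were not planned for this test. On chromosome 1, 39 of 667 genes rose and 475 fell (median −0.48). Chromosomes 13 and 9 had medians of −0.28 and −0.23, and chromosome 8 had 0.29, with 357 rises and 75 falls among 642 genes. The 5 tested genes of the Y chromosome rose (median 2.57): Ddx3y from 22.6 ± 0.692 to 92.6 ± 15.4 CPM, Eif2s3y from 6.80 ± 0.615 to 50.8 ± 2.07 CPM, Uty from 6.90 ± 0.497 to 35.0 ± 3.90 CPM, Kdm5d from 4.46 ± 0.831 to 26.5 ± 4.53 CPM and Gm3376 from 0.312 ± 0.171 to 6.35 ± 0.447 CPM (SD, n = 3 each).

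Neighbouring genes moved together: of 576 windows of 20 genes, 37 had a median of at least 0.5 in size (11 higher, 26 lower, on 10 chromosomes, 15 of them on chromosome 1), against at most 2 in 1000 shuffles of gene order, and contrasts within a group gave 0. On chromosome 14, which holds the targeted gene, medians of 9 windows in a row lay above 0 (Thrb to Ngdn, 0.02 to 0.81; the lowest, Tspan14 to Cgrrf1, at −0.01 without knockout replicate 2) and those of the next 9 below (Zfhx2 to Mbnl2, −0.12 to −0.70, with −0.70 in the window of the targeted gene itself). The tables argue against trends on length, GC and expression level (28 windows after their removal, at most 2 in shuffles), gene families (34 with 1 gene kept per family, at most 2) and knockout replicate 2 (32 without it, at most 3) as the whole source. A difference in DNA copy number between the cells of the groups is a candidate explanation that stays open: in windows picked by their more highly expressed genes alone the other genes shifted by 0.51, and in windows picked by their more lowly expressed genes the others shifted by 0.36 (at most 0.47 and 0.33 in 1000 shuffles), a difference of 0.15, under the bound of 0.3. DNA was not measured. Regional regulation of chromatin and an effect of RAI16 itself were not tested and stay open.

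Knockout replicate 2 stood apart from replicates 1 and 3 of its group. Among 145 genes changed at least 16-fold in the fit without it, it lay nearer to wild type in 0.69%, which argues against a wild-type library under a wrong label. Of the genes that fell as far in that fit, 38 had at least 5 CPM in wild type. Over these, replicate 2 held a median of 0.17% of the excess of wild type (middle range −0.34% to 1.28%), so a share of wild-type cells near 1% stays open. A trend on transcript length removed 31.5% of the variance over genes of its difference from the others, between the bounds of 10% and 50% set for the test, so a length-dependent step in that library may be part of the difference and cannot be told apart from others. The SD over genes of that difference was 0.33 before and 0.27 after the trend was removed, against 0.22 between replicates 1 and 3. The difference of replicate 2 was taken from the mean of replicates 1 and 3, which holds less noise than a single library. The SD of 0.22 is between single libraries, so these values are not on equal terms. No biological explanation was tested.

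The genes that fell at least 16-fold in the libraries labelled knockout could mark a loss of DNA, silencing, or a difference between the clones. Loss of a stretch of DNA with its neighbours would lower the nearest tested genes as well, but the median of 72 such neighbours was −0.16 (middle range −0.66 to 0.24), which argues against it as the general source; loss of single genes stays open. Clones that differ for reasons unrelated to RAI16 cannot be told apart from an effect of the knockout, because the labels name 0 clones and independent clones would be needed. An effect of RAI16 itself stays open and was not tested.

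The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Every other split mixes wild-type with knockout libraries, which turns the difference between the groups into spread within them. Such splits can hardly call single genes, so their counts of 0 were to be foreseen. They also keep part of the real contrast and so do not measure chance for lists or chromosomes. No conclusion is drawn from the splits. The real split gave 7136 genes changed and 1299 changed at least 2-fold, the highest other split gave 0 of each, and 1 of the 10 splits, the real split, was as large. For lists shifted, 9 of 10 splits gave at least the real 4, and the highest other gave 5. For chromosomes, 1 of 10 splits gave as many as the real 12, and the highest other gave 11.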
